A study of Homo sapiens with 18 samples.

How the data were processed

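Total RNA from snap-frozen xenograft tumours was amplified into biotin-labelled complementary RNA and hybridised to Affymetrix U133 Plus 2 arrays, per the labels' protocols. The submitters' processing notes name GCOS, the Affymetrix scanner software; its version, the summarisation and the normalization are not given in the sources used here. The deposited values are log2 intensities of 54675 probe sets on 18 arrays. The log base is not stated and was inferred from the values, which run from 2.69 to 14.56 with no negative value. The array medians lie between 5.168 and 5.208, so the values were used as deposited without further normalization, and all 18 columns were matched to a sample. No 2 arrays held identical values, and replicates of a group correlated at most at 0.996. Detection calls were not analysed here, so depth is expressed only by the number of arrays. The array carries human probes, and RNA of mouse host cells in the tumours can bind some of them.

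Probe sets were named from a platform annotation: 41097 had 1 gene symbol, 1801 several and 11777 none. Of those with 1 symbol, 41043 were found by Entrez identifier in a RefSeq gene table of GRCh38.p14 and 0 symbols needed an update; no coordinates were taken from it. Probe sets above the array's own median on at least 3 arrays were kept, and for each gene the probe set with the highest mean was used, which left 14064 genes. Probe sets with several symbols or none entered only a test of all 32209 probe sets past the filter. BCL3, one of the genes chosen for naming, had 0 probe sets with its symbol alone and was not analysed as a gene here. A probe set that lists BCL3 beside other symbols could enter only the test of all probe sets.

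Limma 3.58.1 in R 4.3.3 was fitted to all 18 arrays with a mean for each of the 6 groups and an intensity trend in the empirical Bayes step, so that the lines shared 1 estimate of spread (12 residual and 4.24 prior degrees of freedom). Contrasts were MEDI5117 minus untreated in each line, their mean over the 3 lines and an F-test of their difference; the 9 untreated arrays were compared between lines with a separate F-test. Limma's t-tests were two-sided, p-values of genes and lists were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 counted as a change. Overlaps of changed genes between lines were tested with one-sided Fisher's exact tests without adjustment. On simulated data of 14064 genes, the fit recovered 30%, 78%, 96% and 100% of changes of 0.5, 1, 2 and 3 on the log2 scale in DU145, 16%, 80%, 98% and 100% in NCI-H1650 and 16%, 72%, 100% and 100% in KPL4. False calls made up 7.32%, 5.16% and 1.37% of the simulated calls. The simulation gave each gene 1 spread for all lines and independent noise. Its rates therefore do not describe a single line, or noise that genes share.

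There were 16 gene lists and 6 lists of cell type markers. The gene lists were IL-6/JAK/STAT3 targets, IL-6 family ligands and receptors, acute-phase proteins, type I interferon response, antigen presentation, NF-kB target cytokines and chemokines, cell cycle, p53 targets and apoptosis, epithelial-mesenchymal transition and invasion, hypoxia and glycolysis, cholesterol biosynthesis, unfolded protein response, oxidative phosphorylation, cytosolic ribosomal proteins, immediate early and heat shock genes, and squamous differentiation. The marker lists were those of fibroblasts, endothelial cells, leukocytes, adipocytes, skeletal muscle and erythroid cells. The epithelial-mesenchymal transition and invasion list is also called the invasion list. It holds epithelial genes such as EPCAM and OCLN beside mesenchymal and protease genes, so its mean gives no direction of the transition. Each was tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over 88 tests. Named genes were the IL-6 axis genes, the 10 largest rises and falls among genes past the test whose groups did not overlap (in the mean of lines, with 1 sign in all 3), the 5 smallest p-values where fewer than 5 passed in a direction, up to 4 members of each list described, and the 10 smallest p-values for a difference between lines. The fit, the lists, the rule for named genes and the alternatives other than those said to be chosen later were set before the data were examined.

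The alternatives were quantile normalization, median centring, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, all probe sets as items, each line's 6 arrays alone, no intensity trend, each array left out in turn, and the replicate number as a block among untreated tumours. Treated and untreated tumours of a line share no replicate number, so the treatment comparisons had no pairing. Alternatives chosen after the data were seen were the 3' over 5' ratio of GAPDH and beta-actin control probe sets as a covariate, array weights estimated gene by gene, 1 array weight per line, and both treated arrays with the lowest upper quartiles left out (NCI-H1650 replicate 5 and KPL4 replicate 5).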

Results

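Gene expression was measured in xenograft tumours grown from 3 human cancer cell lines: DU145, a prostate carcinoma line, NCI-H1650, a lung adenocarcinoma line, and KPL4, a breast carcinoma line. Tumours received MEDI5117, a human antibody that neutralises interleukin 6 (IL-6) and was built to persist in the circulation, at 30 mg/kg for 2 doses. Each line had 3 arrays of treated tumours and 3 arrays of control tumours, 18 arrays in all. The sample labels call the controls untreated, whereas the treatment protocol and the design text describe an isotype control antibody, so the control is named untreated here with that discrepancy open. Nothing in the labels ties the arrays to separate animals, so the p-values measure the spread between these samples, which can be technical in part. The series asks what blocking IL-6 does to the expression programme of tumours of different origin.

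The arrays gave 54675 probe-set intensities each on a log2 scale, with array medians between 5.17 and 5.21, and 14064 genes were tested. The number of arrays limits the precision; with 1 spread pooled over the lines, the median standard error of a within-line change was 0.17 on the log2 scale. Simulated 2-fold changes were recovered for 78% of genes in DU145, 80% in NCI-H1650 and 72% in KPL4. The simulation used 1 spread per gene for all lines, so these values do not compare the lines. Replicates were closest in DU145, where the median standard deviation within a group over genes was 0.10 in treated and 0.10 in untreated tumours. The corresponding values were 0.22 and 0.22 in NCI-H1650 and 0.20 and 0.19 in KPL4. The log2 ratio of 3' to 5' signal of GAPDH and beta-actin, a measure of RNA integrity, ranged from 0.29 to 0.69 over the DU145 arrays, from 0.49 to 1.88 in NCI-H1650 and from 0.74 to 2.78 in KPL4. Its group means were close: 0.44 ± 0.20 treated against 0.48 ± 0.20 untreated in DU145, 1.41 ± 0.20 against 1.31 ± 0.73 in NCI-H1650, and 1.84 ± 0.94 against 1.80 ± 0.93 in KPL4 (SD, n = 3 each).

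**Figure D1:**
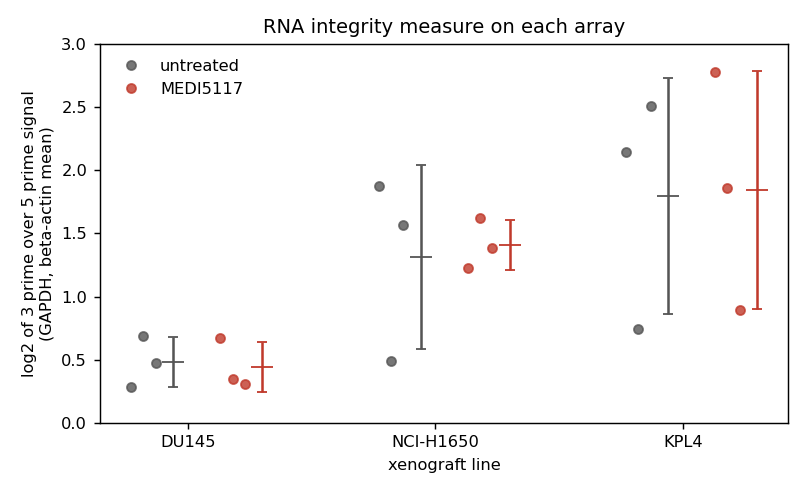
Log2 ratio of 3' to 5' signal, averaged over the GAPDH and beta-actin control probe sets (vertical axis), for each array of the 3 lines (horizontal axis); points are arrays, and bars give the mean and SD of 3 arrays. The ratio spans 0.74 to 2.78 in KPL4 and 0.29 to 0.69 in DU145, while treated and untreated means lie close together in each line.

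In the untreated tumours 9 of 16 genes of the IL-6 pathway differed in level between the 3 lines. IL6ST, the shared signalling receptor subunit gp130, had a log2 intensity of 11.41 ± 0.09 in DU145, against 9.25 ± 0.45 in NCI-H1650 and 9.32 ± 0.42 in KPL4 (SD, n = 3). OSMR, the oncostatin M receptor subunit that pairs with gp130, was also highest in DU145 at 11.76 ± 0.03, with 10.44 ± 0.39 in NCI-H1650 and 9.36 ± 0.33 in KPL4. IL6 itself was highest in NCI-H1650 at 7.32 ± 0.56, with 6.30 ± 0.41 in DU145 and 6.47 ± 0.04 in KPL4, and LIFR, the leukaemia inhibitory factor receptor, was highest in DU145 at 7.67 ± 0.10. By limma's F-test with Benjamini-Hochberg adjustment over the 9 untreated arrays, the lines differed in IL6ST (adjusted p = 4.81e-05), OSMR (1.74e-05), LIFR (7.76e-06), JUNB (0.000128), CEBPD (0.000977), JAK1 (0.00561), MYC (0.0103), IL6 (0.0161) and IL6R (0.0257). SOCS3, the feedback inhibitor of IL-6 signalling that STAT3 induces, stood at 6.89 ± 0.02, 6.71 ± 0.18 and 6.84 ± 0.12 in DU145, NCI-H1650 and KPL4, and its level did not pass the test (adjusted p = 0.445). Neither did STAT3 (0.1), PIM1 (0.196), LIF (0.0668), IL11 (0.143), JAK2 (0.0690) and SOCS1 (0.155). In all, 9617 of 14064 genes (68.4%) differed among the untreated lines.

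In DU145 tumours acute-phase genes were lower under MEDI5117. BPIFA1, a secreted protein of airway epithelium, had the largest fall, from 10.58 ± 0.36 to 7.89 ± 0.44 (6.44-fold lower, SD, n = 3). Haptoglobin (HP) was 5.09-fold lower and the fibrinogen chains FGB and FGA were 3.94-fold and 3.55-fold lower. S100A8 and S100A9, the subunits of calprotectin, were 4.12-fold and 3.86-fold lower. SOCS3 fell from 6.89 ± 0.02 to 5.59 ± 0.04, a 2.46-fold difference.

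By limma's moderated test with Benjamini-Hochberg adjustment, 30 genes changed in DU145, 4 higher and 26 lower in treated tumours, 17 of them at least 2-fold. In each of the 30 genes the 3 treated arrays lay on one side of the 3 untreated arrays; over all genes tested this held for 15.4%, where chance gives 10%. The log2 changes were -2.69 ± 0.24 for BPIFA1 (SE; adjusted p = 2.71e-05), -2.35 ± 0.18 for HP (4.99e-06), -2.15 ± 0.33 for the chitinase-like gene CHI3L2 (0.00568) and -2.04 ± 0.25 for S100A8 (0.000814). The S100A8 change ranged from -2.21 to -1.15 over the alternatives. Further falls were FGB with -1.98 ± 0.24 (0.000787), S100A9 with -1.95 ± 0.24 (0.000814), FGA with -1.83 ± 0.18 (8.63e-05) and DMBT1, a mucosal scavenger protein, with -1.68 ± 0.16 (5.35e-05). S100P fell by 1.51 (adjusted p = 0.0102), SERPINA1, which encodes alpha-1 antitrypsin, by 1.48 (0.0128) and SOCS3 by 1.30 ± 0.20 (0.00568). The genes that rose were HMGN2P46, with 0.95 (0.0451), the transporter ABCA8 with 0.94 (0.0334), KIAA1217 with 0.79 (0.00913) and SPINK2 with 0.70 (0.0235). HMGN2P46 is a pseudogene whose probes can read related transcripts. Its call was lost without any 1 of 15 of the 18 arrays (adjusted p up to 0.321), that of ABCA8 without 11 (up to 0.246), that of SPINK2 without 5 (up to 0.188), and that of KIAA1217 without 3 (up to 0.0875) and as the mean of its probe sets (0.99995, where the alternatives began at 1.55e-06). TDRD10 was 0.68 higher and did not pass (0.0797). The axis genes IL6 (-0.18), IL6R (0.08), IL6ST (0.10), STAT3 (-0.29), JUNB (-0.43), CEBPD (-0.56), PIM1 (-0.06) and MYC (0.06) did not pass either, each with an adjusted p of 1. Treated and untreated arrays of JUNB and CEBPD lay apart. The spread pooled over the lines is wider than DU145's own, so these tests can miss changes in that line. For a typical gene it is narrower than the spread of NCI-H1650 or KPL4, which favours calls in those lines. The counts of changed genes therefore do not rank the lines by the strength of their response.

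Among the gene lists, acute-phase proteins stood out in DU145: 20 of 22 measured members were lower, with a mean log2 change of -0.73, and 4 fell over all genes tested (FGA, FGB, HP and SERPINA1) or 11 adjusted over the list alone. Camera, limma's test of a list against the other genes, gave an adjusted p of 1.06e-28, and adjusted p = 0.0279 with an estimated correlation. IL-6/JAK/STAT3 targets had a mean of -0.16 with 23 of 36 members lower (camera adjusted p = 8.56e-07); SOCS3 alone fell, also when adjusted over the list alone, and the call was lost at adjusted p = 0.0933 with an estimated correlation. LCN2, an acute-phase and STAT3 target gene, was 0.60 lower and did not pass (adjusted p = 1 in limma's test), and OSMR was 0.41 lower (1) with separate groups. The type I interferon list had 26 of 38 members lower and a mean of -0.16 (camera adjusted p = 2.51e-06), with adjusted p = 0.424 with an estimated correlation. Its 2 members that fell, over all genes and adjusted over the list alone, were IFITM2 (-0.94, limma adjusted p = 0.00372) and IFITM3 (-0.79, 0.00549), interferon-induced proteins that restrict virus entry and are so alike that their probe sets can read each other's transcripts. With gene-by-gene array weights, chosen after the data were seen, the interferon mean was -0.0806 and its call was lost as well (adjusted p from 2.61e-07 to 0.629 over the alternatives).

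The leukocyte markers had a mean of -0.32 in DU145 but a median of 0.04 over 11 measured members (camera adjusted p = 0.00213; adjusted p = 0.0619 with an estimated correlation). Its 2 members that fell, over all genes and adjusted over the list alone, were S100A8 and S100A9, which squamous epithelium makes as well as neutrophils; the integrin ITGB2 was 0.39 higher and did not pass (limma adjusted p = 1). The same 2 genes were the falls of the squamous differentiation list, whose mean was -0.14 and median 0.02 (camera adjusted p = 0.0473; adjusted p = 0.394 with an estimated correlation), a call kept under only 2 of 11 alternatives (adjusted p from 0.000753 to 0.4999), and the keratin KRT4 was 0.35 higher without passing (limma adjusted p = 1). Of the erythroid markers 3 were measured, with a mean of -0.19, and none fell (camera adjusted p = 0.00879; adjusted p = 0.176 with an estimated correlation). Without the filter the leukocyte and erythroid calls were lost too, with means of -0.17 and -0.0975 and the alternatives' adjusted p up to 0.0938 and 0.318. The 46 cell cycle genes had a mean of 0.04 and none changed (camera adjusted p = 0.584). DU145's tumours varied less than the others, and with 1 weight per line, an alternative chosen after the data were seen, 172 genes changed, 75 higher and 97 lower, against 65 higher and 106 lower on the line's own 6 arrays. The count was 16 without MEDI5117 replicate 7, 18 without MEDI5117 replicate 8 and 10 without untreated replicate 3, the last of which also took SOCS3 past the threshold (adjusted p = 0.0561), as did averaging its probe sets (0.193, where the alternatives ranged from 9.75e-07 to 0.193).

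In NCI-H1650 tumours SOCS3 had the largest fall of the genes that passed, from 6.71 ± 0.18 to 4.63 ± 0.48 (4.25-fold lower, SD, n = 3). OSMR was 2.27-fold lower and JUN, a subunit of the AP-1 transcription factor, was 1.62-fold lower. CHST15, a chondroitin sulfotransferase, and the transcription factor ETS2 were 1.99-fold and 1.73-fold lower. SUSD2, a membrane protein gene, was 2.7-fold higher and TMC5, a transmembrane channel-like gene, was 2.22-fold higher.

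By limma's moderated test with Benjamini-Hochberg adjustment, 10 genes changed in NCI-H1650, 3 higher and 7 lower, 4 of them at least 2-fold, and 1073 genes had an unadjusted p under 0.05. In each of the 10 the treated and untreated arrays were separate, which held for 6.60% of all genes tested, where chance gives 10%. SOCS3 changed by -2.09 ± 0.20 (SE; adjusted p = 0.000171) and OSMR by -1.18 ± 0.19 (0.0284). CHST15 fell by 0.99, C1RL, a C1r-like protease gene, by 0.90 and ETS2 by 0.79 (each 0.00924), JUN by 0.70 (0.0496) and the matrix gene VWA1 by 0.64 (0.0447). JUN and VWA1 each lost the call under 7 of 11 alternatives that kept all or left out 2 arrays, with adjusted p from 0.00532 and 0.00839 up to 0.9999. The rises were SUSD2 with 1.43 ± 0.21 (0.00924), TMC5 with 1.15 ± 0.20 (0.0447) and TST, the sulfurtransferase rhodanese, with 0.69 ± 0.12 (0.0447). TST lost the call under 5 of the same 11 alternatives, TMC5, C1RL and ETS2 under 3 and CHST15 under 2 (each with adjusted p up to 0.9999), OSMR under 3 (up to 0.792) and SUSD2 under 2 (up to 0.238). MTARC1 (0.60) and PAIP2B (0.77) were higher and did not pass (adjusted p = 0.106 each). IL6 (-0.34), IL6R (0.08), IL6ST (-0.41), STAT3 (-0.23), JUNB (-0.06), CEBPD (-0.22), PIM1 (-0.11) and MYC (-0.35) did not pass, with adjusted p from 0.686 to 0.984.

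Several gene lists passed camera's test in NCI-H1650 at the preset correlation of 0.01, while few of their members passed singly. The estimated correlation was 0.44 for the interferon list and 0.43 for the hypoxia list. It was 0.05 for the epithelial-mesenchymal transition and invasion list, the only one that passed in this line with an estimated correlation. The p-values at the preset correlation can therefore be too small. Type I interferon response genes were lower in 36 of 38 members, with a mean log2 change of -0.44 (camera adjusted p = 1.31e-13; adjusted p = 0.176 with an estimated correlation). None of them fell over all genes and 2 did adjusted over the list alone, IFITM2 (-0.57, limma adjusted p = 0.159 over all genes) and IFITM3 (-0.57, 0.106); IFI44L was at -0.92 (0.351) and CMPK2 at -0.98 (0.423). Genes of the epithelial-mesenchymal transition and invasion list had a mean of -0.39 with 25 of 37 lower (camera adjusted p = 2.31e-06; adjusted p = 0.0494 with an estimated correlation). Of these 0 fell over all genes and 10 adjusted over the list alone; fibronectin (FN1) was at -1.85 (limma adjusted p = 0.0509), MMP3 at -1.52 (0.196), MMP2 at -0.96 (0.190) and the transcription factor TWIST1 at -0.83 (0.142). Hypoxia and glycolysis genes had a mean of -0.37 with 34 of 37 lower (camera adjusted p = 1.62e-08; adjusted p = 0.314 with an estimated correlation). In that list 0 fell over all genes and 5 adjusted over the list alone, among them the glycolytic regulator PFKFB3 (-0.92, limma adjusted p = 0.0836) and the glucose transporter SLC2A1 (-0.57, 0.338). The hypoxia mean was -0.19 without both treated arrays of lowest upper quartile, left out after the data were seen.

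IL-6/JAK/STAT3 targets in NCI-H1650 had a mean of -0.35 with 30 of 36 lower (camera adjusted p = 1.70e-08; adjusted p = 0.0619 with an estimated correlation). SOCS3 and OSMR fell over all genes and 5 members adjusted over the list alone, including TNFRSF1A, which was at -0.48 (limma adjusted p = 0.165). The IL-6 family list had a mean of -0.20 (camera adjusted p = 0.0126; adjusted p = 0.129 with an estimated correlation), with OSMR as its fall and LIF at -0.86 (limma adjusted p = 0.268), and 2 members fell adjusted over the list alone. Acute-phase genes had a mean of -0.30 and a median of -0.09 (camera adjusted p = 0.0163; adjusted p = 0.564 with an estimated correlation), with 0 falls over all genes and 5 adjusted over the list alone; SERPINA1 was at -1.15 (limma adjusted p = 0.125) and SERPINA3 at -1.46 (0.195). Another SERPINA1 probe set, not the one used for the gene, changed by -1.40 (limma adjusted p = 0.0162 over all probe sets). NF-kB target cytokines and chemokines had a mean of -0.25 (camera adjusted p = 0.00194; adjusted p = 0.494 with an estimated correlation), which ranged from -0.56 to -0.21 over the alternatives, with 0 falls over all genes and 1 adjusted over the list alone, PTGS2, the inducible cyclooxygenase (-1.18, limma adjusted p = 0.0912). Antigen presentation genes had a mean of -0.20 with 22 of 27 lower (camera adjusted p = 0.00213; adjusted p = 0.296 with an estimated correlation). The IL-6 family call was also lost with the mean of a gene's probe sets and the acute-phase call without the filter.

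The lists on the higher side in NCI-H1650 were those of oxidative phosphorylation, cholesterol biosynthesis and adipocytes. All 34 measured oxidative phosphorylation genes were higher, by a mean of 0.15 (camera adjusted p = 3.06e-07; adjusted p = 0.138 with an estimated correlation); 0 rose over all genes and 1 adjusted over the list alone, NDUFA1 (0.30, limma adjusted p = 0.214), with NDUFB9 at 0.22 (0.450). Cholesterol biosynthesis genes had a mean of 0.14 with 17 of 19 higher (camera adjusted p = 0.000852; adjusted p = 0.322 with an estimated correlation), and adipocyte markers a mean of 0.20 over 7 genes (camera adjusted p = 0.0301; adjusted p = 0.129 with an estimated correlation). The adipocyte call was lost under 8 of 11 alternatives, with adjusted p from 0.0229 to 0.243 and a mean from 0.14 to 0.50, and the cholesterol mean ranged from 0.12 to 0.28. The 46 cell cycle genes had a mean of -0.04 and none changed (camera adjusted p = 0.641). In a limma fit of the line's own 6 arrays 0 genes changed, with 415 at an unadjusted p under 0.05, and with 1 weight per line, chosen after the data were seen, SOCS3 alone did; SOCS3 itself did not pass on the 6 arrays or as the mean of its probe sets (adjusted p from 4.37e-05 to 0.164 over the alternatives). Single arrays moved the count of 10 between 1, without MEDI5117 replicate 4, and 98, without untreated replicate 1, whose label marks a repeated hybridisation; without MEDI5117 replicate 5 it was 45, with 29 higher and 16 lower.

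**Figure D2:**
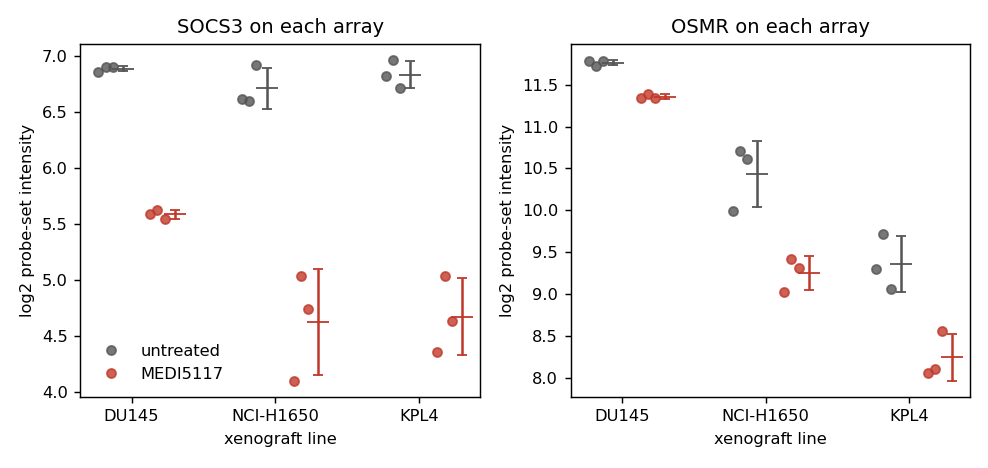
Log2 probe-set intensity (vertical axis) of SOCS3 and OSMR on each array of the 3 lines (horizontal axis); points are arrays, and bars give the mean and SD of 3 arrays. SOCS3 lay near 6.8 in every untreated group and at 5.59 in treated DU145, 4.63 in treated NCI-H1650 and 4.67 in treated KPL4; the OSMR change passed limma's test in NCI-H1650 and KPL4.

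In KPL4 tumours SCGB1A1, the club cell secretoglobin, went from 4.89 ± 0.34 to 7.38 ± 0.46 (5.60-fold higher, SD, n = 3), and KRT13, a keratin of stratified epithelia, was 3.46-fold higher. The proteases MMP3 and MMP1 were 4.92-fold and 4.91-fold lower, FGB was 4.65-fold lower and PTGS2 was 2.94-fold lower. SOCS3 fell from 6.84 ± 0.12 to 4.67 ± 0.34, a 4.48-fold difference. OSMR and the cytokine genes IL24 and IL1B were 2.16-fold, 2.74-fold and 1.96-fold lower.

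By limma's moderated test with Benjamini-Hochberg adjustment, 71 genes changed in KPL4, 33 higher and 38 lower, 28 of them at least 2-fold. The groups were separate in all 71, and in 13.0% of all genes tested, where chance gives 10%. The largest rises were SCGB1A1 with 2.49 ± 0.20 (SE; adjusted p = 8.17e-06), the metallophosphoesterase gene MPPED2 with 1.79 ± 0.13 (2.12e-06), KRT13 with 1.79 ± 0.28 (0.00548) and RCSD1 with 1.58 ± 0.14 (2.30e-05). CALML5, a calmodulin-like protein of skin, rose by 1.48 (0.000190), the cytochrome P450 gene CYP2F1 by 1.33 (3.38e-05), the mucin MUC19 by 1.29 (0.0171), the WNT inhibitor APCDD1 by 1.27 (0.0275), the mammary cytochrome P450 gene CYP4Z1 by 1.17 (0.0414) and the secretoglobin SCGB1D2 by 1.13 (0.0396). SCGB1D2 lost its call under 3 of 10 alternatives (adjusted p up to 0.438), and with gene-by-gene array weights, chosen after the data were seen, its change was 0.48. CYP4Z1 lost it under 2 of 10 (up to 0.481) and MUC19 and APCDD1 under 1 of 10 each (up to 0.416 and 0.0539), as did KRT13 (0.286) and, of 11, CALML5 (0.146). The largest falls were MMP3 with -2.30 ± 0.38 (0.00997), MMP1 with -2.29 ± 0.36 (0.00548), FGB with -2.22 ± 0.24 (0.000145), SOCS3 with -2.16 ± 0.20 (2.31e-05) and PTGS2 with -1.55 ± 0.23 (0.00435). Further falls were IL24 with -1.46 (0.000848), the antimicrobial ribonuclease RNASE7 with -1.45 (2.31e-05), the transglutaminase TGM2 with -1.30 (0.0166), A2M with -1.30 (0.0224) and the defensin DEFB1 with -1.23 (0.00997). TGM2 and A2M each lost the call under 3 of 11 alternatives (up to 0.0956 and 0.286) and were at -0.71 and -0.64 as the mean of their probe sets. PTGS2 and DEFB1 each lost it under 1 of 11 (up to 0.284 and 0.147) and IL24 under 1 of 10 (up to 0.135). The axis genes other than SOCS3 did not pass: IL6 was at -0.82 (0.752) with separate groups, and IL6R (0.21), IL6ST (-0.30), STAT3 (-0.33), JUNB (-0.38), CEBPD (-0.52), PIM1 (-0.15) and MYC (-0.26) had adjusted p from 0.364 to 1. STAT3 and CEBPD had separate groups too. IL6 ran from 5.58 to 5.73 on the treated and from 6.44 to 6.52 on the untreated KPL4 arrays. The pooled spread of IL6 also holds the treated NCI-H1650 arrays, which ran from 6.12 to 8.54. The test can therefore miss a change of IL6 in KPL4.

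IL-6/JAK/STAT3 targets were lower in 34 of 36 members in KPL4, with a mean of -0.40 (camera adjusted p = 1.54e-13; adjusted p = 0.0317 with an estimated correlation). SOCS3, OSMR (-1.11, limma adjusted p = 0.0120) and the protease inhibitor TIMP1 (-0.90, 0.0348) fell, and 5 members fell adjusted over the list alone. OSMR lost its call under 3 of 11 alternatives (adjusted p up to 0.284) and TIMP1 under 2 (up to 0.289). Acute-phase genes had a mean of -0.49 with 17 of 22 lower (camera adjusted p = 1.25e-08; adjusted p = 0.138 with an estimated correlation). FGB, A2M, FGA (-1.22, limma adjusted p = 0.00435) and the lipopolysaccharide-binding protein LBP (-1.20, 0.00874) fell, and 7 members did adjusted over the list alone. FGA lost its call under 2 of 11 alternatives (up to 0.135), with -0.61 as the mean of its probe sets, and LBP under 3 of 10 (up to 0.147). NF-kB target cytokines and chemokines had a mean of -0.45 with 23 of 29 lower (camera adjusted p = 2.79e-09; adjusted p = 0.176 with an estimated correlation). PTGS2 and IL1B (-0.97, limma adjusted p = 0.0258) fell and 8 members did adjusted over the list alone, CXCL8 being at -1.07 (0.111); IL1B lost its call under 2 of 11 alternatives (up to 0.295). The invasion list had a mean of -0.33 with 29 of 37 lower (camera adjusted p = 6.44e-06; adjusted p = 0.0577 with an estimated correlation); MMP1 and MMP3 fell, and 3 members did adjusted over the list alone.

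Other lists were lower in KPL4 with few or no members past the test. Unfolded protein response genes had a mean of -0.21 with 26 of 30 lower (camera adjusted p = 6.31e-07; adjusted p = 0.0894 with an estimated correlation), 0 falls by either count and EDEM1 at -0.49 (limma adjusted p = 0.158). Immediate early and heat shock genes had a mean of -0.26 (camera adjusted p = 5.51e-07; adjusted p = 0.108 with an estimated correlation); JUN fell by 0.60 (limma adjusted p = 0.0400), and 3 members did adjusted over the list alone. Hypoxia genes had a mean of -0.22 with 30 of 37 lower (camera adjusted p = 8.63e-06; adjusted p = 0.435 with an estimated correlation), 0 falls by either count and the lipase inhibitor ANGPTL4 at -0.99 (limma adjusted p = 0.191). Without both treated arrays of lowest upper quartile, left out after the data were seen, the hypoxia mean in KPL4 was -0.045 (camera adjusted p = 0.204, with alternatives from 5.62e-07 to 0.489). Fibroblast markers had a mean of -0.26 with 14 of 16 lower (camera adjusted p = 0.000402; adjusted p = 0.223 with an estimated correlation); COL6A3, a collagen chain, fell by 0.80 (limma adjusted p = 0.0470), PDGFRB was at -0.45 (0.206), and 2 members fell adjusted over the list alone. COL6A3 lost its call under 4 of 10 alternatives (limma adjusted p from 0.00129 to 0.330). Leukocyte markers had a mean of -0.23 (camera adjusted p = 0.0140; adjusted p = 0.122 with an estimated correlation), 0 falls over all genes and 2 adjusted over the list alone, LAPTM5 (-0.93, limma adjusted p = 0.0511) and S100A9 (-0.83, 0.210). The IL-6 family list had a mean of -0.16 (camera adjusted p = 0.0200; adjusted p = 0.138 with an estimated correlation), with OSMR as its fall by both counts and LIF at -0.72 (limma adjusted p = 0.302). The IL-6 family call was kept under 7 of 11 alternatives (camera adjusted p up to 0.157), and the fibroblast and leukocyte calls each under 8 (up to 0.288 and 0.182), with means from -0.28 to -0.16 and from -0.34 to -0.11.

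The squamous differentiation list did not shift as a whole in KPL4 (mean 0.10, median 0.02, camera adjusted p = 0.353). Fry's PValue tests whether a list's genes move on balance one way and its PValue.Mixed whether they change in either direction, without comparing the list with other genes; the mixed adjusted p was 6.53e-05. KRT13 rose over all genes and 5 members rose and 1 fell adjusted over the list alone, with KRT5 at 1.35 (limma adjusted p = 0.0568) and KRT4 at 0.95 (0.0755). In the p53 and apoptosis list (mean -0.03, camera adjusted p = 0.550) the pro-apoptotic gene BMF rose by 0.61 (limma adjusted p = 0.0386) and the death receptor gene TNFRSF10B fell by 0.58 (0.0348), the same pair as adjusted over the list alone. BMF lost its call under 5 of 10 alternatives (adjusted p up to 0.312) and TNFRSF10B under 5 of 11 (up to 0.380). Interferon response genes had a mean of -0.00 (camera adjusted p = 0.697) and the 46 cell cycle genes a mean of 0.07 (0.222), with none changed in either. A limma fit of the line's own 6 arrays gave 11 genes and 1 weight per line, chosen after the data were seen, gave 34, against 71, while the 3' over 5' ratio in the fit, also chosen later, gave 300 and the filter at the 75th percentile 46. The pooled spread is narrower than that of KPL4 for a typical gene, so the 71 calls do not show a stronger response than in DU145. Single arrays moved the count of 71 between 26, without KPL4 MEDI5117 replicate 6, and 138, without NCI-H1650 MEDI5117 replicate 5.

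**Figure D3:**
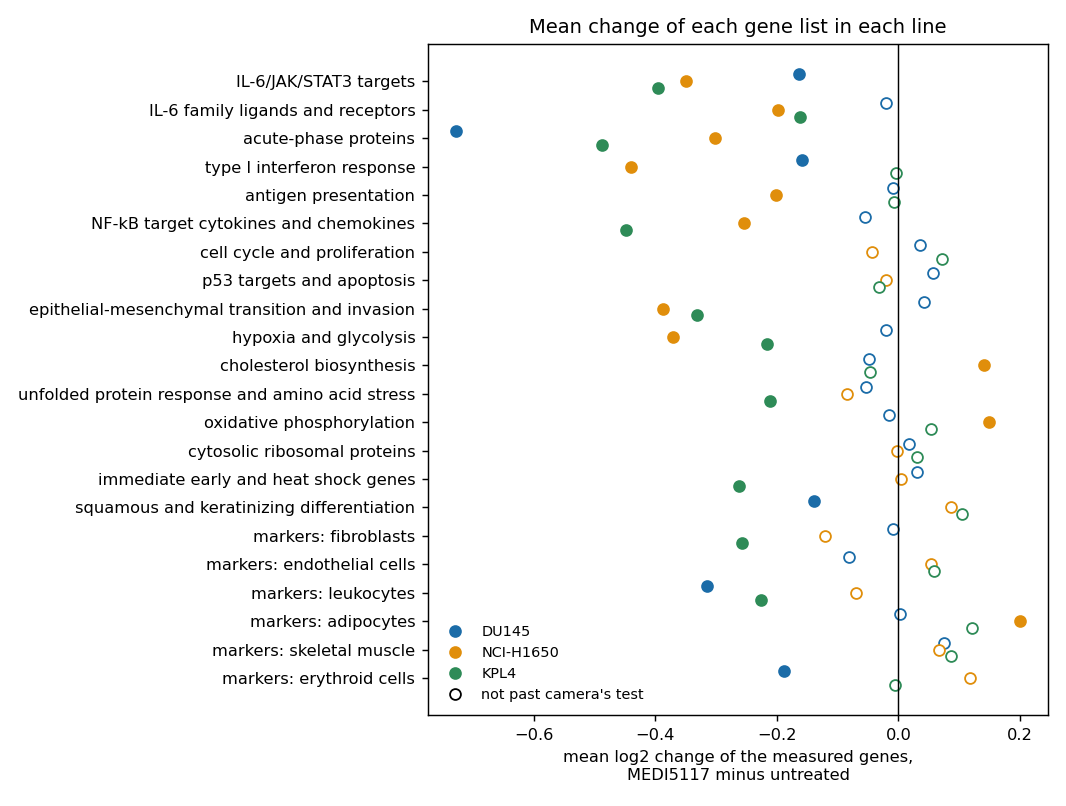
Mean log2 change of the measured genes of each of 22 lists (horizontal axis, MEDI5117 minus untreated) in each line; filled points passed camera's test after Benjamini-Hochberg adjustment and open points did not. Acute-phase proteins had the lowest mean in DU145 (-0.73) and IL-6/JAK/STAT3 targets were lower in all 3 lines (-0.16, -0.35 and -0.40), with adjusted p = 0.0933, 0.0619 and 0.0317 with an estimated correlation.

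Averaged over the 3 lines, SOCS3 and acute-phase genes were lower under MEDI5117. None of the 22 measured acute-phase genes passed in NCI-H1650, where 13 were lower and 9 higher, with a median log2 change of -0.09. FGA was at -1.83 in DU145, -0.09 in NCI-H1650 and -1.22 in KPL4. SOCS3 was 3.61-fold lower and the same sign was seen in every line. SERPINA1, FGA and MMP1 were 2.21-fold, 2.06-fold and 2.34-fold lower, and OSMR, PTGS2 and complement factor I (CFI) were 1.87-fold, 1.90-fold and 1.88-fold lower. Among the genes with 1 sign in all 3 lines, SCGB1A1 rose 1.88-fold and CALML5 1.60-fold. Both rises lay mainly in KPL4. SCGB1A1 was at 0.10 in DU145, 0.15 in NCI-H1650 and 2.49 in KPL4 on the log2 scale, and CALML5 at 0.07, 0.49 and 1.48.

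In the mean of 3 lines limma's moderated test with Benjamini-Hochberg adjustment gave 60 genes, 16 higher and 44 lower, 6 of them at least 2-fold. Of the 60, 42 had the same sign of change in all 3 lines, which held for 27.8% of all genes tested. Choosing genes by a large mean change favours a shared sign by itself. SOCS3 changed by -1.85 ± 0.12 (SE; adjusted p = 2.95e-07), MMP1 by -1.23 ± 0.21 (0.00801), SERPINA1 by -1.15 ± 0.14 (0.000780), FGA by -1.04 ± 0.11 (0.000128) and CFI by -0.91 ± 0.09 (7.46e-05). PTGS2 fell by 0.93 (0.00265), CHI3L2 by 0.91 (0.0424), OSMR by 0.90 (0.000777), TGM2 by 0.81 (0.00801) and NNMT, nicotinamide N-methyltransferase, by 0.72 (0.00801). Of the 16 rises 8 had 1 sign in all 3 lines: beside SCGB1A1 (0.91, 0.000936) and CALML5 (0.68, 0.00210) these were CYP4F3 (0.67, 0.0341), ARRDC4 (0.45, 0.0313), KIAA1217 (0.43, 0.00979), CLIC3 (0.40, 0.00801), CREB3L4 (0.38, 0.00612) and ST6GALNAC4 (0.31, 0.0424). The other 8, singled out after their values were seen, lacked 1 sign in all lines, among them APCDD1 (0.80, 0.0148), MPPED2 (0.62, 0.000599), RCSD1 (0.54, 0.00404) and CYP2F1 (0.53, 0.00210). Among the 8 with 1 sign, the changes of SCGB1A1, CALML5 and CREB3L4 differed between lines by limma's F-test and were largest in KPL4. ST6GALNAC4 lost its call under 3 of 10 alternatives (up to 0.113) and CYP4F3 under 1 of 10 (up to 0.0738). KIAA1217 was at 0.19 as the mean of its probe sets (adjusted p = 0.402, with alternatives from 0.000347). STAT3 was at -0.28 (0.0882), CEBPD at -0.44 (0.146), IL6 at -0.45 (0.773), JUNB at -0.29 (0.633), IL6ST at -0.20 (0.914), IL6R at 0.12 (0.868), PIM1 at -0.10 and MYC at -0.18 (0.999 each), and none of these passed.

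IL-6/JAK/STAT3 targets were lower in 32 of 36 members in the mean of 3 lines, with a mean of -0.30 (camera adjusted p = 2.98e-19; adjusted p = 0.0214 with an estimated correlation). SOCS3 and OSMR fell over all genes and 13 members adjusted over the list alone; TNFRSF1A was at -0.32 (limma adjusted p = 0.0501). Acute-phase genes had a mean of -0.51 with 19 of 22 lower (camera adjusted p = 1.17e-19; adjusted p = 0.0473 with an estimated correlation), and FGA, FGB (-1.34, limma adjusted p = 0.000128), HP (-0.79, 0.000936) and SERPINA1 fell, or 12 members adjusted over the list alone. The invasion list had a mean of -0.23 (camera adjusted p = 1.18e-07; adjusted p = 0.0400 with an estimated correlation); MMP1 and MMP3 (-1.27, limma adjusted p = 0.0111) fell, and 8 members fell and 1 rose adjusted over the list alone. Leukocyte markers had a mean of -0.20 (camera adjusted p = 0.000729; adjusted p = 0.0494 with an estimated correlation), with a median of -0.10, where S100A8 (-0.78, limma adjusted p = 0.0198) and S100A9 (-0.91, 0.00413) fell and 3 members did adjusted over the list alone. S100A8 lost its call as the mean of its probe sets (limma adjusted p = 0.130), and its change was as small as -0.49 over the alternatives. The leukocyte call was lost without the filter (mean -0.093, adjusted p = 0.0938, the highest over the alternatives, which began at 0.000140). FGB, HP, MMP3, S100A8 and S100A9 did not have 1 sign in all 3 lines. Single arrays moved the count of 60 between 40, without DU145 MEDI5117 replicate 8, and 131, without NCI-H1650 MEDI5117 replicate 5, where 65 were higher and 66 lower. In alternatives chosen after the data were seen, leaving out both treated arrays of lowest upper quartile gave 82 higher and 69 lower, and the 3' over 5' ratio in the fit gave 335 genes.

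Other lists passed in the mean of 3 lines and lost the call with an estimated correlation. Interferon genes had a mean of -0.20 (camera adjusted p = 2.47e-10; adjusted p = 0.267 with an estimated correlation), with IFITM3 (-0.50, limma adjusted p = 0.00148) and IFITM2 (-0.55, 0.00210) falling by both counts. NF-kB targets had a mean of -0.25 (camera adjusted p = 1.34e-08; adjusted p = 0.188 with an estimated correlation); PTGS2 and SOD2 (-0.62, limma adjusted p = 0.0331) fell, 6 members did adjusted over the list alone, and ICAM1 was at -0.80 (0.117). Hypoxia genes had a mean of -0.20 (camera adjusted p = 1.22e-09; adjusted p = 0.276 with an estimated correlation), with 0 falls over all genes and 1 adjusted over the list alone, PFKFB3 (-0.45, limma adjusted p = 0.0679). The IL-6 family list had a mean of -0.13 (camera adjusted p = 0.00374; adjusted p = 0.0894 with an estimated correlation), with OSMR as its fall, 2 members adjusted over the list alone and LIF at -0.60 (limma adjusted p = 0.0790). Immediate early genes had a mean of -0.08 (camera adjusted p = 0.00403; adjusted p = 0.336 with an estimated correlation), where JUN fell by 0.37 (limma adjusted p = 0.0260), though not with 1 sign in all lines. Unfolded protein response genes had a mean of -0.12 (camera adjusted p = 2.12e-05; adjusted p = 0.129 with an estimated correlation), fibroblast markers one of -0.13 (camera adjusted p = 0.00194; adjusted p = 0.296 with an estimated correlation) and antigen presentation genes one of -0.07 (camera adjusted p = 0.0200; adjusted p = 0.434 with an estimated correlation). Oxidative phosphorylation genes were higher, with a mean of 0.06 (camera adjusted p = 0.00194; adjusted p = 0.377 with an estimated correlation). The hypoxia mean ranged from -0.20 to -0.0849 over the alternatives, and the fibroblast mean, whose call was also lost at the 75th percentile filter, from -0.21 to -0.0419; quantile normalization took the antigen presentation call as well. Cytosolic ribosomal proteins, skeletal muscle markers and endothelial markers shifted in no line and not in the mean of lines, with lowest camera adjusted p of 0.550, 0.222 and 0.0842. Of 88 tests of 22 lists and 4 comparisons, 40 passed with camera's preset correlation, 36 of them lower, 7 with an estimated correlation and 8 by fry. The 7 were IL-6/JAK/STAT3 targets in KPL4 and in the mean of lines, acute-phase proteins in DU145 and in the mean, the invasion list in NCI-H1650 and in the mean, and leukocyte markers in the mean. The invasion list mixes epithelial with mesenchymal and protease genes, so its lower mean does not measure invasion.

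SOCS3 was the only gene that passed in each of the 3 lines. DU145 and KPL4 shared 5 lower genes, CFI, FGA, FGB, SOCS3 and SQOR, where independent lists would share 0.0703 (one-sided Fisher's exact test, p = 6.92e-09). NCI-H1650 and KPL4 shared JUN, OSMR and SOCS3, 3 genes against 0.0189 (p = 6.32e-07 by the same exact test), and DU145 and NCI-H1650 shared SOCS3 against 0.0129 (p = 0.0129, exact). The lines share each gene's estimate of spread and genes are not independent, so these exact p-values can be too small. SQOR, a sulfide oxidoreductase, was named after the overlap was seen, and the rule had named CFI only in the mean of 3 lines. JUN lost its call under 7 of 11 alternatives in NCI-H1650 and 5 of 11 in KPL4, and no higher gene was shared by any pair. Across genes, which are not independent replicates, the log2 changes correlated with r = -0.07 between DU145 and NCI-H1650, 0.17 between DU145 and KPL4 and 0.27 between NCI-H1650 and KPL4. The SOCS3 values rest on the probe set with the highest signal of the gene; in the test of all probe sets, the others were at -0.22 (limma adjusted p = 0.570) and -0.10 (1) in the mean of 3 lines. Over the alternatives the smallest SOCS3 change was -0.56 in DU145, -0.74 in NCI-H1650, -0.87 in KPL4 and -0.72 in the mean of 3 lines.

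HP, the gene of haptoglobin, changed by -2.35 in DU145, 0.13 in NCI-H1650 and -0.15 in KPL4, and BPIFA1 by -2.69, 0.10 and -0.26. SCGB1A1 changed by 2.49 in KPL4, against 0.10 in DU145 and 0.15 in NCI-H1650, and MPPED2 by 1.79, against -0.07 and 0.15. FGB was lower in DU145 and KPL4 (-1.98 and -2.22) and at 0.16 in NCI-H1650. TMC5 rose in NCI-H1650 (1.15) and was at 0.15 in DU145 and -0.78 in KPL4.

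By limma's F-test for a difference between the 3 within-line changes with Benjamini-Hochberg adjustment, 18 genes differed, and 750 had an unadjusted p under 0.05. The smallest p-values were those of MPPED2 and HP (adjusted p = 0.000234 each), SCGB1A1 (0.000980), RCSD1 and BPIFA1 (0.00126 each), RNASE7 (0.00229), DMBT1 (0.00303), CYP2F1 (0.00530), FGB (0.00573) and TMC5 (0.0197). RNASE7 changed by -1.45 in KPL4, against -0.04 in each of the other lines, DMBT1 by -1.68 in DU145, against 0.09 and -0.28, RCSD1 by 1.58 in KPL4, against -0.06 and 0.09, and CYP2F1 by 1.33 in KPL4, against 0.28 and -0.03. For SOCS3 and OSMR the changes did not differ by this test (adjusted p = 0.634 and 0.739), so no difference in the size of their fall between lines was shown. Single arrays moved the count of 18 between 9, without NCI-H1650 MEDI5117 replicate 4, and 32, without NCI-H1650 untreated replicate 1. With the 3' over 5' ratio in the fit, added after the data were seen, 54 genes differed. FGB did not pass as the mean of its probe sets (adjusted p = 0.182) or with 1 weight per line (0.0971), with alternatives from 0.000825 to 0.182.

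**Figure D4:**
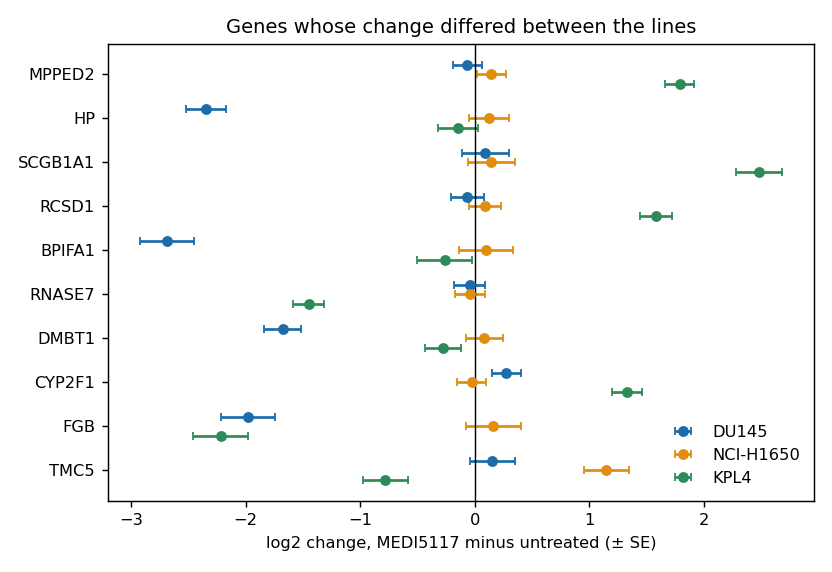
Log2 change (horizontal axis, MEDI5117 minus untreated) of the 10 genes with the smallest p for a difference between lines; points are the fitted changes in each line and bars their standard errors. HP and BPIFA1 lay at -2.35 and -2.69 in DU145 and SCGB1A1 at 2.49 in KPL4, with the other 2 lines near 0.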

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

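The test of leukocyte markers for S100A8 and S100A9, the test of dim probe sets among 46 genes and the fit with the 3' over 5' ratio were chosen only after the results they bear on were seen. The change under MEDI5117 differed between lines, by limma's F-test with Benjamini-Hochberg adjustment, for 15 of the named genes: MPPED2 and HP (adjusted p = 0.000234 each), SCGB1A1 (0.000980), RCSD1 and BPIFA1 (0.00126 each), RNASE7 (0.00229), DMBT1 (0.00303), CYP2F1 (0.00530), FGB (0.00573), TMC5 (0.0197), FGA (0.0215), S100A8 (0.0220), IL24 and CREB3L4 (0.0361 each) and CALML5 (0.0411). FGA changed by -1.83 in DU145, -0.09 in NCI-H1650 and -1.22 in KPL4, and S100A8 by -2.04, 0.37 and -0.68. IL24 was at 0.04, -0.06 and -1.46, CREB3L4 at 0.23, 0.00 and 0.91, and CALML5 at 0.07, 0.49 and 1.48. Of 100 drawn splits within lines, 10 gave as many genes as the 18 that differed, with up to 1301 in another split, so chance cannot be excluded for that count as a whole and a structure of the samples calls many more genes.

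Among 5893 probe sets with no single gene named, which the gene tests leave out, 3 passed in DU145, 1 in NCI-H1650, 6 in KPL4 and 8 in the mean of 3 lines. Those in DU145 changed by -1.94 (limma adjusted p = 0.000535), 0.79 (0.0306) and 0.88 (0.0370), and the one in NCI-H1650 by 0.83 (0.0390). Of the 6 in KPL4, 5 were lower, with changes from -1.84 to 1.91 (limma adjusted p up to 0.0424). Of the 8 in the mean of 3 lines, 7 were lower, with changes from -1.15 to 0.69 (up to 0.0477).

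The 71 genes called in KPL4 came from the line with the widest range of RNA integrity. The group means of the 3' over 5' ratio were close (1.84 and 1.80), which argues against a linear effect of that ratio as their source. With the ratio in the fit all 71 kept their call, and the median of adjusted over unadjusted change was 0.9998. That median follows from the close means and adds no separate support. Integrity that the ratio does not capture, or an effect that is not linear, stays open. Dim probe sets stay open too: 0% of the 71, and 0% of the 46 that pass the filter on the other lines' arrays, had both KPL4 means under the arrays' median, but only 7.94% of all tested genes did, so the filter largely fixes that value. The 10 splits of 6 arrays are too few for a share under 0.05: 2 gave as many genes, the real one with 71 and one with 943, which set the 3 arrays with the highest ratios (2.15 to 2.78) against the rest (0.74 to 1.86) and so points to integrity as a structure of these samples. A response of the tumours to the antibody stays open as a hypothesis.

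The type I interferon list was lower in 36 of 38 members in NCI-H1650, with a mean of -0.44. A shift of all genes could not be tested, since the arrays already share 1 centre. The median change of all genes (-0.0063) follows from that centre. The group means of the 3' over 5' ratio were close (1.41 and 1.31), which argues against a linear effect of that ratio as the source. The list mean of -0.43 with the ratio in the fit had little room to move and adds no separate support. Integrity that the ratio does not capture, or an effect that is not linear, stays open. Whether a single array decides the size could not be settled: without MEDI5117 replicate 4 the mean was -0.24 (standard error 0.03), near 0.5 of its size (-0.22), and without MEDI5117 replicate 6 it was -0.65. That standard error is taken over the 38 genes, which move together, and does not measure the spread between arrays. For the line's genes as a whole the 10 splits are too few for a share under 0.05; 4 gave as many, with 10 genes in the real split and 97 in another, MEDI5117 replicates 4 and 6 with untreated replicate 1, which points to a structure of the samples. A lower interferon response under the antibody may be part of the pattern and was not shown apart from that array.

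S100A8 and S100A9 fell in DU145 by a mean of 1.995, and fewer leukocytes in the treated tumours would lower other leukocyte markers too. The 6 other markers above the arrays' median had a median change of 0.13 (SD 0.16), from -0.09 for FCER1G to 0.39 for ITGB2, which argues against that explanation as far as these markers go. Host leukocytes are murine and human probes read them unequally, so a loss of mouse cells that these probe sets do not register stays open, as does a lower output of both genes by the tumour cells. For DU145 the 10 splits are too few for a share under 0.05: 1 gave as many genes, the real one with 30, and the highest other gave 0.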

How the results depend on the processing

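Array weights, the covariate, 1 weight per line and the fit without both treated arrays of lowest upper quartile were chosen only after the results were seen. Of 82 called changes of named genes, 44 passed under every alternative that kept all arrays or left out both of those, 38 lost the call under at least 1 and none reversed; 40 lost it without at least 1 single array. Of 10 named genes that differed between lines 9 passed under those alternatives, and of 40 called list results 6 did, with none reversed; without at least 1 single array, 1 of the 10 and 14 of the 40 lost the call. For each count that moved and each value that reversed the cause was not tested, except that fewer genes or arrays enter by construction. The number of arrays and the spread between them limit precision; signal over background was not analysed here. Pseudocounts were not run because the values are already log2.

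With median centring NCI-H1650 had 6 genes, 1 higher and 5 lower (83.3% lower, against 70.0%). At the 75th percentile filter KPL4 had 46 and lines differed in 9. With the mean of a gene's probe sets NCI-H1650 had 4, and as single items 20408 probe sets differed among untreated lines. On each line's own 6 arrays limma called 171 genes in DU145, 0 in NCI-H1650 (415 at an unadjusted p under 0.05) and 11 in KPL4. With 1 weight per line (2.49 for DU145, 0.552 for NCI-H1650, 0.726 for KPL4) the counts were 172, 1 and 34, and lines differed in 29. With the 3' over 5' ratio they were 51, 174 and 300, with 335 in the mean and 54 between lines. Without both treated arrays NCI-H1650 had 36 and the mean 151. Gene-by-gene weights gave 391, 27 and 2958, with 1074 in the mean and 991 between lines; they put 7.62 on KPL4 MEDI5117 replicate 6. The planned weights by restricted maximum likelihood did not converge (weight 178 on the same array, 347, 106 and 7038 genes, 1902 in the mean, 2631 between lines) and were not used. Camera with an estimated correlation passed 7 lists and fry 8, against 40. With the replicate number as a block, 9696 genes differed among untreated lines, against 9617, within 1.5 times.

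The share of lower genes also moved. In DU145 (26 of 30 lower) 106 of 171 were lower on its own arrays, 97 of 172 with 1 weight per line and 201 of 391 with gene-by-gene weights. In NCI-H1650 (7 of 10) 16 of 45 were lower without its MEDI5117 replicate 5, 13 of 36 without both arrays and 11 of 27 with gene-by-gene weights. In the mean of lines (44 of 60) 66 of 131, 69 of 151 and 460 of 1074 were lower under the same settings. In KPL4 (38 of 71) 10 of 26 were lower without its MEDI5117 replicate 6, 13 of 36 without untreated 1, 28 of 79 without both arrays and 52 of 81 without untreated 2.

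Signs turned for values that had not passed: cell cycle in NCI-H1650 (0.0166 with quantile normalization, 0.0200 with gene-by-gene weights, 0.0577 without both arrays), squamous differentiation in KPL4 (-0.0297 at the 75th percentile filter) and MYC in KPL4 (0.13 with gene-by-gene weights, 0.18 without both arrays).

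With single arrays left out, DU145 ranged from 10 to 38 genes (16 without its MEDI5117 replicate 7, 18 without 8, 10 without untreated 3). NCI-H1650 ranged from 1 to 98: 1, 45 and 20 without its MEDI5117 replicates 4, 5 and 6, 98 and 3 without untreated 1 and 3, 5 each without DU145 MEDI5117 replicates 7, 8 and 9, DU145 untreated 3 and KPL4 untreated 1, and 6 each without KPL4 MEDI5117 replicate 6 and KPL4 untreated 3. KPL4 ranged from 26 to 138: 26 without its MEDI5117 replicate 6, 36 each without MEDI5117 replicate 5 and untreated 1 and 3, and 138 without NCI-H1650 MEDI5117 replicate 5. The mean ranged from 40 to 131, with 131 without NCI-H1650 MEDI5117 replicate 5, 96 without NCI-H1650 untreated 1 and 40 without DU145 MEDI5117 replicate 8. The count that differed between lines ranged from 9 to 32: 10 each without DU145 MEDI5117 replicate 7, DU145 untreated 3 and KPL4 MEDI5117 replicate 6, 9 without NCI-H1650 MEDI5117 replicate 4 and 32 without NCI-H1650 untreated 1. Cell cycle ranged from -0.00425 to 0.0754 in DU145 and from -0.14 to 0.0790 in NCI-H1650. In DU145 IL6 ranged from -0.39 to 0.0197 and PIM1 from -0.13 to 0.0128. In NCI-H1650 IL6 ranged from -1.12 to 0.0838, IL6R from -0.0422 to 0.20, JUNB from -0.28 to 0.18, CEBPD from -0.51 to 0.0618, PIM1 from -0.30 to 0.0908 and MYC from -0.60 to 0.0108. In KPL4 MYC ranged from -0.66 to 0.22 and PIM1 from -0.55 to 0.13.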

Other observations

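The test of acute-phase genes against their untreated level was chosen only after the result was seen. The genes that differed between lines beyond the named ones were TNFSF10, B3GALT5 and TFF3 (limma adjusted p = 0.0361 each), singled out after their values were seen. TNFSF10, which encodes the death ligand TRAIL, changed by -1.18 in DU145, -0.26 in NCI-H1650 and 0.40 in KPL4. TFF3, a trefoil peptide secreted by mucosal epithelium, changed by -0.10, -0.18 and 0.81, and the galactosyltransferase B3GALT5 by -0.08, 0.12 and 0.97.

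The hypothesis was that acute-phase genes with the highest untreated probe-set intensity fall most. The rank correlation between untreated intensity and change over 22 genes was -0.66 in DU145, -0.70 in NCI-H1650 and -0.22 in KPL4. In 10000 random lists of 22 genes the 5th percentile was -0.31, -0.51 and -0.39, so 2 of the 3 lines lay below it, DU145 and NCI-H1650. The correlation lay at percentile 0.03 of the random lists in DU145, 0.23 in NCI-H1650 and 19.9 in KPL4. The untreated intensity enters both measures, which draws such a correlation below 0 in the random lists as well. These values do not decide it, since KPL4 did not follow and intensities of different probe sets are not comparable as levels of expression.

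In the mean of 3 lines 60 genes changed, and 4 of 100 drawn splits within lines gave as many, the real one included. That share is under 0.05, but too narrowly for so few drawn splits to exclude chance. The highest other split gave 2545 genes, many times the real count, which points to a structure of the samples. Among the untreated lines 9617 genes differed, 1 of 100 drawn splits gave as many and the highest other gave 3667, so chance is excluded.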
